A study of Mus musculus with 5 samples.

How the data were processed

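The 5 samples were grouped by their labels into 4 ChIP groups and 1 WCE group of 1 sample each. The WCE file was analysed here, and the ChIP samples were not. Per the submitters' processing notes, the WCE reads were aligned with Bowtie 0.9.9.2 and the build was mm8. The alignment options, read filters and base caller are not given in the sources used here. The deposited file listed 1 alignment per line in the layout of Bowtie's default output, with read name, strand, chromosome, position, bases, base qualities, a whole number for further placements, and mismatches. These values are positions and carry no normalization by the authors, so all read counts were made here by counting alignments. Coordinates are mm8 and are printed counting from 1.

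The file listed at most 2 placements of a read. How reads with more placements were treated by the authors is not given in the sources used here. Read names ended in 0 or 1, a digit whose meaning is not given there either. Reads with 1 placement whose name ended in 0 had 1.95 mismatches on average, against 0.352 for those ending in 1. Both were kept for density, and reads ending in 1 were used for mismatches.

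Before the data were examined, the density of X, the share of repeated starts, and results on promoters, gene bodies, Hox clusters, gene lists, named genes and a transgene check were planned. The rule for named genes was a fixed list plus the 10 genes with the most promoter reads. No reference genome was used here. The gene table at hand was of another build than mm8, so none of its coordinates were used and no gene was named. The results on promoters, gene bodies, Hox clusters, gene lists and the transgene were therefore not computed. The plan did not say how to treat reads with 2 placements. The main read set was reads with 1 placement, with 1 read kept per start and strand, and values with the other reads are given beside it. The share of repeated starts was computed over all alignments, as planned.

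Reads were counted in bins of 100 kb from 3 Mb on. X density was the median bin of X over the median autosomal bin. For GC correction, each bin was given the mean GC of its own reads, and its count was divided by the median of autosomal bins in the same class of 2 percentage points, using classes with at least 20 autosomal bins of at least 50 reads. Read GC stood in for the GC of the reference, so this correction counts as an alternative added after seeing the data. It can absorb real differences in density that go with GC. A first version left out bins with under 50 reads when chromosome levels were taken, which removed more bins from X than from the autosomes. That restriction was dropped, and its values are given as alternatives. Runs of bins were searched with a minimum of 3 bins, against the median of all bins of the chromosome.

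For the CpG comparison, 20 windows of 10 kb with over 400 distinct reads were left out and a seeded random split made seeds and partners. For mismatches, bases of quality 30 or more in the first 25 cycles were compared in 1 Mb bins with at least 20000 such bases, which leaves 50 bins on X. Agreement of the third read was measured at positions covered by exactly 3 such bases where at least 2 showed the same mismatch. It was computed as the chance that any further read shows a mismatch that a pair of reads shares. Agreement of pairs was measured at positions covered by exactly 2 such bases where either showed a mismatch, as the share of mismatching bases whose partner showed the same one, so that a shared position counts with both of its bases.

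No test across samples was possible with 1 library. Intervals of counts, rates, shares and ratios of counts were exact Poisson or exact binomial (Clopper-Pearson) at 95%. For X density, the interval of the total X count was scaled to the ratio of medians, so it leaves out the error of the medians. Intervals for ratios of percentiles or medians over 1 Mb bins may also be too narrow, because neighbouring bins share levels. A jackknife over autosomes is named where it was used. The methods were tested on simulated data. A chromosome made at 0.5 of the autosomal copy number was recovered at 0.496 after GC correction and at 0.389 before it. Every simulated read could be placed, so the effect of the lower share of placeable reads on X was not tested this way. Agreement of the third read was recovered as 0.999 at homozygous sites and 0.496 at heterozygous sites, each simulated alone and not mixed. Alternatives changed the read set, strand, bin size, thresholds, base quality and cycles. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.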

Results

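The study profiled chromatin in progenitor motor neurons made in culture from mouse embryonic stem (ES) cells. Chromatin immunoprecipitation with sequencing (ChIP-seq) was labelled for 3 histone marks, H3K27me3, H3K4me3 and H3K79me2, and for RNA polymerase II. One further library, a whole-cell extract (WCE), was sequenced without antibody as the background against which ChIP signal is read. Each of the 5 groups held 1 sample. The WCE file was used, and the 4 ChIP libraries were not analysed here. The WCE came from day 5 cells of the Ainv15 line, an ES line built for inducible transgenes, whereas the ChIP samples were labelled as day 4 cells of the HBG3 line. The control therefore differed from the ChIP samples in both line and day. The protocol also describes a tagged Cdx2 insertion in this line, without saying whether the cells of this library carried or induced it. The protocol describes patterning on day 2 with 1 µM retinoic acid, a caudalising and neuralising signal, and 0.5 µM of a hedgehog agonist (SAG), a ventralising signal. With 1 library there was no replicate check and no p-value was computed. The 95% intervals of counts, rates and shares cover counting error only, and no interval covers variation between libraries.

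The WCE file held 17068489 alignments of 13409439 reads of 36 bases. Of these reads, 9750389 had 1 listed placement in the genome and 3659050, or 27.3% (exact binomial 95% interval 27.3 to 27.3%), had 2. Reads with 1 placement occupied 9570301 distinct combinations of start and strand, a mean of 3.72 per kb over the autosomes and X. Those reads were split evenly between the strands, with 49.98% (49.94 to 50.01%) on the plus strand. Among reads with 2 placements, 73.4% (73.4 to 73.5%) of the first listed placements were on the plus strand.

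The share of alignments at a start position already taken was 15.3% (15.3 to 15.3%) over all alignments. Among reads with 1 placement it was 1.85% (1.84 to 1.86%). A small number of places held much of this excess. The 79 windows of 1 kb with at least 1000 alignments held 6.99% of all alignments, and without them the share was 9.22%.

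The X chromosome was covered less densely than any autosome. The median 100 kb bin held 106 reads on X and 343 on the autosomes, a ratio of 0.309. The interval given for it (0.308 to 0.311) is the exact Poisson interval of the total of 183223 X reads, scaled to the ratio. The error of the medians themselves was not measured, and X bins had quartiles of 81 and 142 reads. The 19 autosomes ranged from 0.872 on chromosome 3 to 1.31 on chromosome 11, with an SD of 0.110 across autosomes, and X lay below all of them. Reads rose with GC content across autosomal bins, from a median of 208 reads at 36% GC to 869 at 56% GC. X was the most AT-rich chromosome by its reads, with a median bin GC of 40.7%. After division by the median of autosomal bins of like read GC, the autosomes ranged from 0.933 on chromosome 7 to 1.02 on chromosome 16 (SD 0.0218), and the ratio of X to the autosomes was 0.435. X also had fewer placeable reads: a median of 48.4% of reads in its bins counted as distinct reads with 1 placement, against 80.8% on the autosomes. In bins with at least 80% such reads, 155 on X and 12532 on autosomes, the GC-corrected ratio was 0.512. With all alignments counted as deposited the uncorrected ratio was 0.664, so the level of X depended on which placements were counted, while every setting run left X under the autosomal median.

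**Figure D1:**
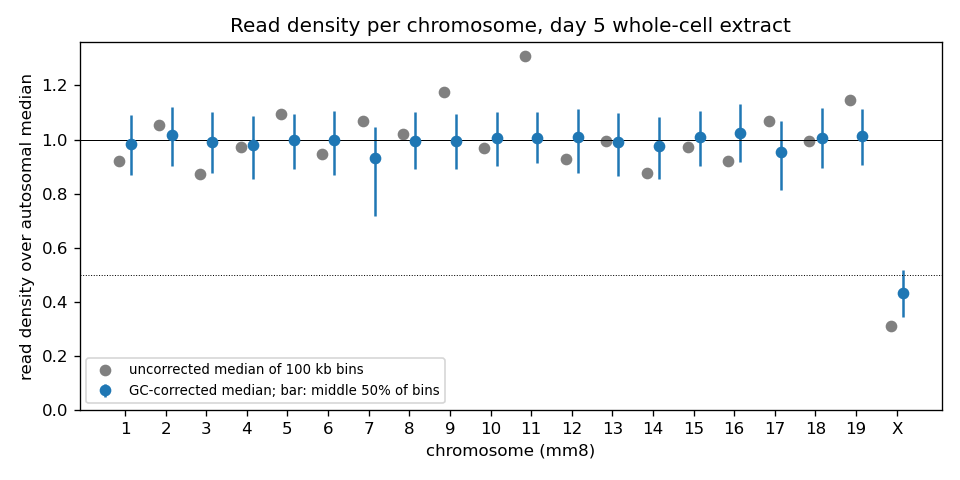
Median read density of 100 kb bins per chromosome relative to autosomes in the day 5 WCE library, before (grey) and after (blue) correction for read GC, with bars for the middle 50% of bins and lines at the autosomal level and at 0.5. X lies at 0.309 before correction and below every autosome.

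The assembled Y chromosome was covered at a level close to that of X. The median 10 kb bin held 9 reads on Y, over 272 bins, 10 on X and 33 on the autosomes. Y carried 2834 distinct reads with 1 placement. These medians were not corrected for GC or placement.

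Stretches of raised density were searched along the chromosomes, a search chosen after the data were seen. Runs of at least 3 bins of 100 kb over 1.4 times the GC-corrected level of their chromosome numbered 7. This number depended strongly on some settings: 32 at a threshold of 1.3, 3 at 1.6 and 715 without GC correction. It was 13 on the plus strand, 9 on the minus strand, 5 with repeated starts kept and 6 for read names ending in 1. After shuffling bins within chromosomes 1000 times at the main settings, the mean was 0.311 runs and the highest 3. Of the 7 runs, 2 were on the autosomes. The longer, at chromosome 17 from 30100001 to 30700000 (mm8), held 5948 reads at 1.89 times the chromosome's level (1.84 to 1.94), against a median of 1.17 in the 5 bins on each side. The other, at chromosome 9 from 46600001 to 46900000, held 2788 reads at 2.21 times the level (2.12 to 2.29), against 1.08 beside it. In these regions 86.0% and 94.0% of reads counted as distinct with 1 placement. The remaining 5 runs were on X. Of these, 3 were at 1.55, 1.47 and 1.48 times the level, from 12700001 to 13000000, from 48500001 to 48800000 and from 147300001 to 147600000, where 79.1%, 90.2% and 71.1% of reads counted as distinct with 1 placement. The run from 138500001 to 138900000 reached 1.67, with 11.4% such reads. The run from 165100001 to 165400000 reached 5.22, with 31.6% such reads, through 1 bin at 7.23, while its median bin was at 1.62. The runs on X depended on the level of X, which bins with few placeable reads lowered. When chromosome levels were taken only from bins with at least 80% single placement, an alternative added after seeing the data, 2 runs were found, the autosomal ones, at 2.10 (2.03 to 2.18) on chromosome 9 and 1.74 (1.69 to 1.78) on chromosome 17. The 3 X runs named first were then at 1.20, 1.15 and 1.15 times the level, the fourth was under 1.4, and the fifth was at 4.06 through its 1 high bin. With levels from bins with at least 50 reads, 4 runs were found, and the 3 X runs named first were the ones lost. The loss was marginal: they were still at 1.48, 1.41 and 1.41 times the level as a whole. Genes in these regions are not named, because no annotation of this build was used.

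**Figure D2:**
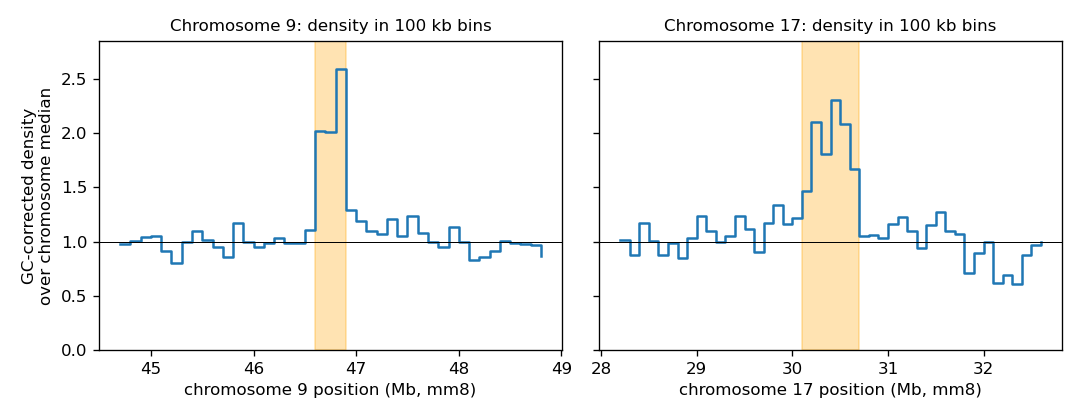
GC-corrected read density in 100 kb bins, relative to the chromosome median, around the autosomal runs on chromosomes 9 and 17 (shaded; mm8 positions in Mb). The shaded regions average 2.21 and 1.89 times the level of their chromosome.

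In most regions of low density, few of the reads had 1 placement. Runs of at least 3 bins under 0.65 of the level numbered 203, and in 200 of them under 60% of reads counted as distinct with 1 placement. The other 3, at 80.5%, 85.8% and 64.7%, were on chromosome 1 from 184800001 to 185200000, chromosome 12 from 42100001 to 42500000 and chromosome 13 from 92400001 to 93200000, beside bins at 1.08, 1.14 and 1.01 times the level. Of their bins, 3 of 4, 3 of 4 and 6 of 8 held no alignment at all, as did at least 1 bin in 9 of the 200. Without the genome, gaps in the assembly could not be told from DNA missing in these cells or from reads the file does not list. The count of distinct reads with 1 placement sets both the density and the share of such reads. A low share therefore goes partly with a low density by construction, and does not show that placement lowered it.

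Reads with 1 placement lay more densely near CpG-dense reads than 2 to 5 kb away. This comparison was also chosen after the data were seen, since promoters could not be located without the genome. CpG dinucleotides are rare in mouse DNA outside CpG islands, which overlap many promoters, where H3K4me3 and polymerase signal is usually read. Autosomal reads were divided at random into seeds and partners. Around 90351 seeds with at least 4 CpG, partners lay at 10.7 per kb within 500 bp and at 3.30 per kb from 2 to 5 kb away, a ratio of 3.24 (3.23 to 3.25). Around 2846655 seeds without CpG the ratio was 1.13 (1.13 to 1.13), and it rose with each further CpG, to 1.61 for seeds with 2 and 2.20 for seeds with 3. Across the 19 autosomes the ratio for CpG-dense seeds ranged from 2.83 to 3.90 (SD 0.339). The intervals treat pairs of reads as independent, which they are not, so the spread across autosomes is the wider guide to error. Seeds are themselves reads, so dense places contribute more seeds, with or without CpG. Neither the near nor the distant counts were corrected for the share of positions where a read can have 1 placement. The value at seeds without CpG also depended on their surroundings: it was 1.27 where at least 3 other seeds lay within 500 bp, and 1.90 where the mean GC of those seeds also matched that around CpG-dense seeds, against 3.34 at CpG-dense seeds with as many other seeds near them.

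**Figure D3:**
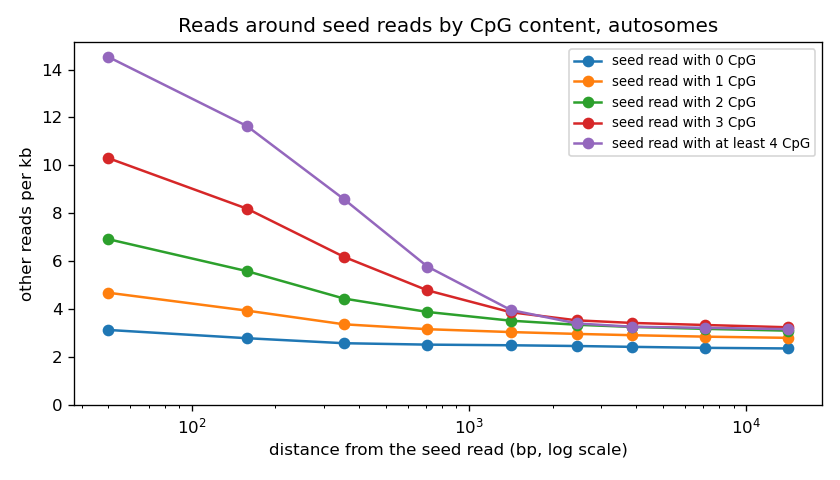
Partner reads per kb against distance from seed reads (bp, log axis) on autosomes, with 1 line per number of CpG in the seed. Density around seeds with at least 4 CpG falls from 14.5 per kb within 100 bp to 3.39 per kb at 2 to 3 kb, while around seeds without CpG it goes from 3.12 to 2.45.

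Among spacings of at least 50 bp, reads on opposite strands faced each other most often at 100 to 110 bp, at 1.57 times the mean count at 800 to 1000 bp. The excess fell to under 50% of its height at 260 bp. The peak was broad, at 1.52 times that mean at 50 to 60 bp and 1.51 times at 150 to 160 bp. The labels give an average fragment of about 500 bp after sonication. The spacing is one between separate reads and not a measured fragment length, so it does not test that label.

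The WCE reads also carried bases that differed from the reference, counted here in 2388 bins of 1 Mb. The rate per 1000 bases of quality 30 or more had a median of 2.49 and ran from 0.928 at the 5th percentile to 9.23 at the 95th.

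**Figure D4:**
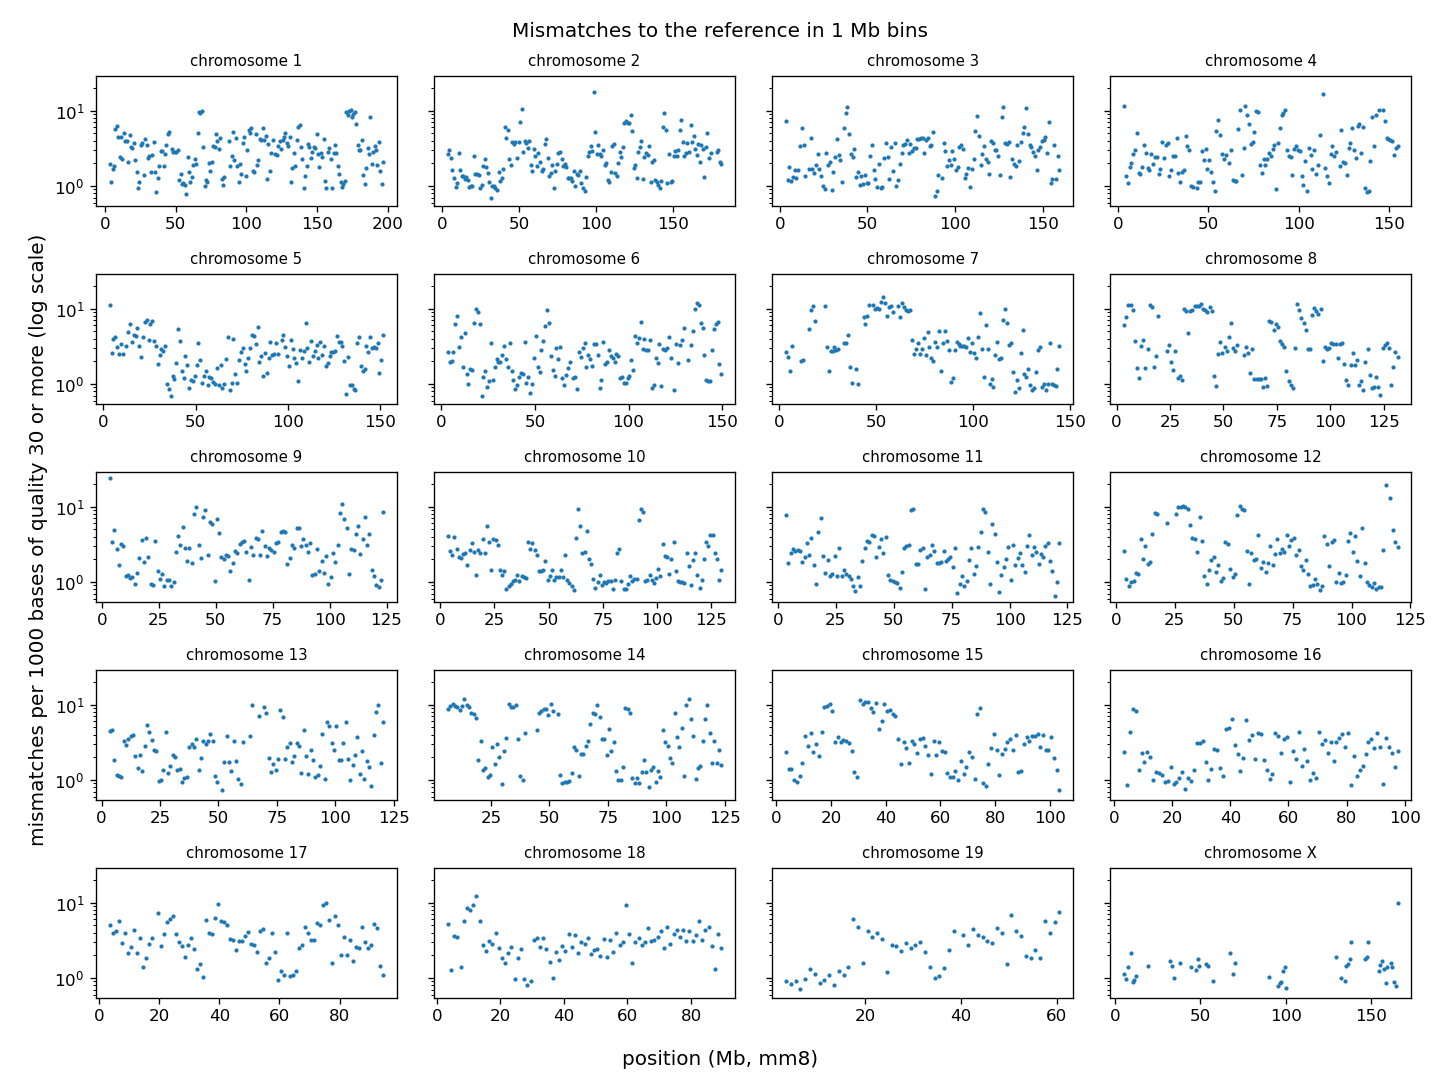
Mismatches to the reference per 1000 bases of quality 30 or more in 1 Mb bins (1 point per bin; log axis) along the autosomes and X (mm8 positions in Mb). Neighbouring bins share levels, as on chromosome 14 from 6000001 to 19000000 at 9.09, and X, with 50 bins, has 1.70 overall.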

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

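Both tests of the mitochondrial strand excess below were chosen only after the result was seen, and nothing in this part was planned. The signals are described here because mitochondrial and unplaced alignments, and placements of reads listed at 2 sites, did not enter the densities of X and the autosomes in the main read set, although all of them entered the share of repeated starts.

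On the mitochondrial chromosome, 66.0% of 1599 distinct reads with 1 placement were on the minus strand (63.7 to 68.4%), while such reads were evenly split over the whole library. Repeated starts were not the whole cause, because that 66.0% was measured with 1 read per start and strand, down from 70.3% with repeats. Autosomal reads had more G than C as sequenced 1.54 times as often as the reverse, and this preference alone predicts 57.8% minus-strand reads for the mitochondrial sequences. That lies between the bounds set for and against it, so a preference for G may account for part of the excess, and the rest cannot be told apart from other sources here. No biological explanation was tested.

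The unplaced part of the Y chromosome received 467927 alignments, or 2.74% of all, against 5193 reads with 1 placement.

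The 10 fullest windows of 1 kb held 4.37% of all alignments. The fullest, at chromosome 2 from 98467001 to 98468000, held 199885 alignments, of which 446 were distinct reads with 1 placement.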

How the results depend on the processing

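Alternatives for X by strand, by 1 Mb bins and with all alignments, and the one leaving out mitochondrial and unplaced sequences, were planned, and all others were chosen after the data were seen. Counting intervals are narrow at this depth, so most alternatives fell outside them, and the cause was not tested unless the setting itself shows it. For X, the interval is that of the total count, so a value just outside it need not differ from the main ratio of medians. X density stayed under 1 in all settings: 0.304 on the plus strand, 0.316 on the minus strand, 0.304 in 1 Mb bins, 0.305 for read names ending in 1, 0.664 with all alignments, 0.613 with reads of 2 placements kept and collapsed, 0.435 with GC correction, 0.452 with that correction without bins under 50 reads, and 0.512 with it in bins of at least 80% single placement. The share of repeated starts was 15.1% without mitochondrial and unplaced sequences, 1.85% for reads with 1 placement and 9.22% without the fullest windows. The CpG ratio stayed above 2: 2.63 with at least 3 CpG, 3.76 with at least 6, 3.87 within 250 bp, 2.49 within 1000 bp, 3.54 with repeated starts, 3.48 with the fullest windows kept, 3.20 for names ending in 1, 3.23 with seeds and partners exchanged, and 3.23 with ends moved 100 bp. The number of high-density runs went from 7 to 32 at a threshold of 1.3, 3 at 1.6, 3 in 50 kb bins and 715 without GC correction. With chromosome levels from bins of at least 50 reads it was 4, and from bins of at least 80% single placement 2, both on autosomes. By read set it was 13 on the plus strand, 9 on the minus strand, 5 with repeated starts kept and 6 for names ending in 1. Agreement of the third read was 97.7% at quality 20, 95.4% on the plus strand and 94.8% on the minus strand. The spread of mismatch rates was 8.06 at quality 20, 6.23 over 36 cycles and 9.53 with all read names. No paired analysis was possible because each group had 1 sample. Alternatives set beforehand that need a reference genome were not run, among them total X reads over mappable positions, correction by reference GC, and those for promoters, gene bodies, Hox clusters and gene lists.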

Other observations

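The mismatch and CpG results below were chosen after the data were seen. Of their tests, those on diverged copies and on base composition of the surrounding kilobase were set before their results were seen, and those on sequencing error, mixed genomes, GC of the seed read and windows with very many reads only after.

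Differences from the mm8 reference came in blocks along the chromosomes. Over 149165086 bases of quality 30 or more there were 3.02 mismatches per 1000 bases. The 5th percentile of 2388 bins of 1 Mb was 0.928 and the 95th was 9.23, a ratio of 9.94 (9.69 to 10.2). The ratio was lower with other settings, at 8.06 for quality 20 and 6.23 over 36 cycles. Sequencing errors count as mismatches here and were not subtracted, so the lowest rates may be largely errors. Bins in the highest 10%, over 6.44 per 1000 bases, formed 28 stretches of at least 3 neighbouring bins, against a mean of 5.80 and at most 13 after shuffling rates within chromosomes. A bin with too few bases to measure ended a stretch. On chromosome 7, 20 measured bins in a row from 45000001 to 68000000, with 3 unmeasured bins among them, were all in the highest 10%, at 10.1 mismatches per 1000 bases (9.88 to 10.2). Chromosome 14 held a stretch of 13 bins from 6000001 to 19000000 at 9.09 (8.84 to 9.34), and chromosome 8 one from 34000001 to 45000000 at 10.2 (9.90 to 10.4). At the other end, chromosome 12 from 106000001 to 113000000 had 0.885 (0.822 to 0.951). X had 1.70 over its 50 bins.

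In weighing these blocks, errors made independently in each read were argued against by positions covered by exactly 2 reads: in bins of the highest 10%, of the reads showing a mismatch there, 86.7% (86.0 to 87.3%) had it in the other read too (5816 positions in both reads, 1789 in 1), against 61.2% elsewhere (60.6 to 61.8%). Over all bins, where 2 of 3 reads shared a mismatch, the third showed it in 97.1% of cases (96.5 to 97.6%). There were 1390 positions where 3 reads agreed and 125 where 2 did. The value is far from what 2 genomes mixed in equal parts would give. It was pooled over all bins, and positions where 3 reads agreed had 3 times the weight of the others. A minority of sites or blocks that differ in only 1 copy could therefore go unseen. On X the value was lower, at 83.0% (65.2 to 93.1%) from 13 and 8 such positions, and the reason was not tested. Diverged copies stacked on one site would raise density. The median GC-corrected density of bins in the highest 10% was instead 0.939 times that of the others (0.924 to 0.947). This median speaks to those bins as a set, and reads the file does not list are not counted in it. It cannot exclude stacked copies in single bins, such as the bin of chromosome 2 that holds the fullest window. A candidate explanation left open is that the line carries inherited stretches that differ from the strain of the reference in both copies, which may be what a mosaic ancestry of laboratory mice gives, but no strain comparison was run.

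For the crowding of reads around CpG-dense reads, 3 technical sources were weighed. At equal GC of the seed read, the ratio with at least 4 CpG was at least 1.76 times that with 0 CpG in each of 3 GC classes, which argues against seed GC as the whole cause. The ratio was 3.48 with windows of 10 kb with over 400 distinct reads kept, and 3.24 with them left out. Those windows therefore did not carry the ratio. Without the 1% of seeds with the most neighbours as well, the ratio was 3.12. This last value decides little, because the limit of 400 reads already caps the neighbours of a seed. Leaving out 1% of seeds could then remove only part of the ratio. Seeds with 0 CpG and like GC around them, read from at least 3 neighbouring seeds, had 0.569 of the ratio at CpG-dense seeds (0.548 to 0.590, jackknife over autosomes), which argues against base composition of the kilobase as the whole cause, though it may give part of it. With more neighbours required, the GC is less noisy but dense places are favoured. The value then rose, to 0.594 at 5, 0.639 at 10 and 0.664 ± 0.0363 (jackknife SE) at 15, a check added after the first result. At 15 it lay within its SE of the bound set beforehand against this source. The size of the part from base composition is therefore not settled. GC of the seed and GC of its kilobase were matched in separate comparisons, so the values do not argue against both acting together. Easier shearing of open chromatin was not tested, nor were differences in placeable positions between near and distant places.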
